A study of Mus musculus with 9 samples.

How the data were processed

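RNA came from 9 mouse pancreatic tumour cell lines at passages 10 to 15. Per the labels' protocols, a sequencing service isolated the small RNAs, built the libraries and multiplexed all of them in 1 lane, and reads were single-end with 50 cycles. The genome build was mm10, per the submitters' processing notes. The aligner, the counter and the miRNA annotation are not given in the sources used here.

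The authors deposited raw read counts for 1202 rows, each a mature miRNA at a precursor, which cover 1049 mature names. 918 rows are 5p arms, 114 are 3p arms and 170 have no arm in the name. Rows of 5p arms hold 98.1% of the counts, so statements on a family cover mainly 5p arms. 479 names have 0 reads in every library. The authors also deposited RPM values, which equal the raw count per 1000000 reads of 18 to 30 nt of the library, and averages of these over groups. Their p-value column for Dicer mutant against wild type was deposited in the same table. A second deposited table gives the raw reads and the reads of 18 to 30 nt of each library, where some values of the latter are not whole. In the deposited table the average headed p53 wild type equals wt/wt replicate 2 in every row, while the labels and the series design give all lines floxed Trp53.

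62 mature names occur in several rows. For 34 the rows are identical in every library, for 12 they lie within 5% and for 16 they are further apart, so the same reads were largely counted at each precursor. As fixed before the data were examined, identical rows were kept once and other rows of a name were summed for the tests. The printed CPM levels and the miRNA share use the most-read row of each name, a choice made after seeing this. A CPM is a read count per 1000000 miRNA reads of the library. Names with near-identical sequences, such as miR-669a-5p and miR-669p-5p, also share reads.

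The groups are the Dicer genotypes of the labels, with replicates numbered in label order. Each line is a separate line, but nothing states that each came from a separate animal, and 1 title number occurs in both genotypes, so p-values measure the spread between these lines. Counts were tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment at 5%. 152 miRNAs passed the filter. DESeq2 1.42.0 and voom of limma 3.58.1 were alternatives, as were other size factors, filters, features, the title series as a block, and each library left out. Where DESeq2 gave no adjusted p, none was filled in. 21 miRNA lists were fixed before the data were examined, and the 13 with 2 or more tested members were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. Single values were compared with exact permutation tests of the genotype labels over 126 splits. Detected miRNAs were counted after thinning to the smallest library. Log2 CPM used a prior count of 1 (alternatives were a prior count of 5, TMM-scaled CPM and reads of 18 to 30 nt as library size), and arm ratios a prior of 0.5.

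The count test was tested on simulated counts drawn with the means and library sizes of the real miRNAs, with 200 changed by known folds. The spread was the fitted one for tested miRNAs and its median for the others, or a dispersion of 0.05, far below the fitted one. With the fitted spread 193 simulated miRNAs passed the filter and with 0.05 188 did, against 152 real ones, so the simulation does not match the data in full. With a dispersion of 0.05 it found 18 of 20 2-fold (90%) and 20 of 20 4-fold changes among the changed miRNAs that passed the filter. The rest of the 200 did not pass it and were not tested. Wilson 95% intervals of shares and the limit of 3 counts for a 0 cover counting error only, since reads without molecular identifiers are not independent molecules.

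miRNAs were named by a rule fixed before the data were examined. In each direction it takes up to 10 past the threshold, or where fewer than 5 pass, the 5 with the smallest unadjusted p. It adds the 10 most abundant, the 3 most abundant tested members of each list, and a fixed set with miR-451a, miR-21a-5p and miR-34a-5p. Precursor positions come from the RefSeq genes of GRCm38, the assembly also called mm10, and host genes from GENCODE M21 on the same strand. Wt/wt replicates 2 and 4 were also left out together, because the deposited table lists one as p53 wild type and the other lacks miRNAs that every other library holds.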

Results

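Small RNAs were sequenced from 9 low-passage cell lines, each grown from a mouse pancreatic tumour. The tumours arose in C57BL/6 mice that express the avian virus receptor TVA from the elastase promoter. Pancreatic Cre recombinase in these mice deletes floxed alleles of Trp53, the gene of the tumour suppressor p53. Infection with an avian retrovirus carrying the polyoma middle T oncogene on postnatal day 3 started the tumours. 5 lines came from mice with 1 floxed and 1 wild-type copy of Dicer (Dicer flox/wt) and 4 from mice with both copies wild type (Dicer wt/wt). Dicer is the enzyme that cuts most miRNA precursors into mature miRNAs, and the comparison asks which miRNAs differ after loss of a single copy. The Dicer transcript itself was not analysed here, so the genotype labels could not be checked against it. The libraries held 6352324 to 18391443 raw reads, and 143243 to 1831088 reads assigned to miRNAs. A count of 0 in a library allows up to 1.64 (the deepest) to 20.9 (the shallowest) CPM (counts per 1000000 miRNA reads).

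The share of small RNA reads that were miRNAs was lower on average in the Dicer flox/wt lines, but the lines of each genotype varied widely. Of the reads of 18 to 30 nt, 9.73% ± 7.97 (SD, n = 5) were miRNA reads in Dicer flox/wt and 30.1% ± 17.9 (SD, n = 4) in Dicer wt/wt. The difference of -20.4 percentage points did not pass an exact two-sided permutation test (p = 0.0635). The flox/wt lines held 23.7%, 8.24%, 5.59%, 6.84% and 4.24%, and the wt/wt lines 44.2%, 45.3%, 8.39% and 22.5%, in replicate order. The Wilson 95% interval, which covers counting error alone, was 4.22% to 4.26% for flox/wt replicate 5. The line titles fall into a series of 4-digit and a series of 5-digit numbers, which the labels do not call batches. In the 4-digit series the means were 12.5% (n = 3) and 44.8% (n = 2), in the 5-digit series 5.54% (n = 2) and 15.5% (n = 2), and in each series every wt/wt line lay above every flox/wt line. An exact permutation within the series gave p = 0.0333, the smallest that its 60 splits allow. Without flox/wt replicate 1 the difference was -23.9 points (exact permutation p = 0.0286), and without any 1 of the other 8 lines the exact permutation p was 0.0714 to 0.143. The percent of raw reads that fell within 18 to 30 nt was 40.9% ± 2.95 (SD, n = 5) and 38.9% ± 2.08 (SD, n = 4), a difference that did not pass (exact permutation p = 0.27).

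**Figure D1:**
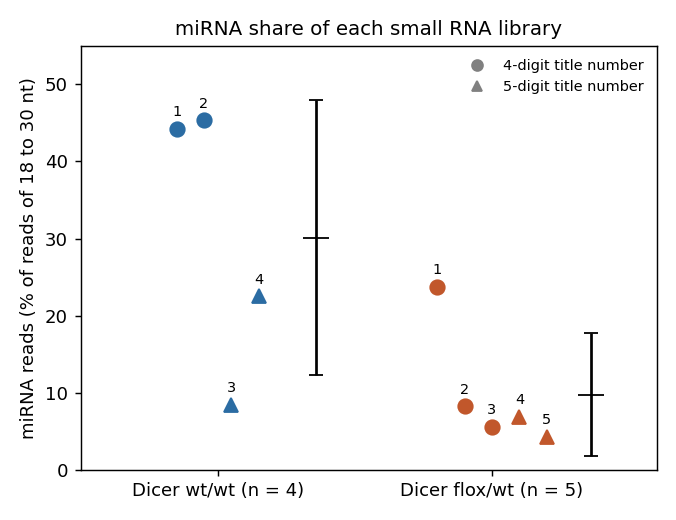
miRNA reads as a percent of the reads of 18 to 30 nt (vertical axis) in each library of the 2 Dicer genotypes (horizontal axis), with replicate numbers, symbols for the title number series, and the mean with SD as bars. The flox/wt mean is 9.73% and the wt/wt mean 30.1%, and the ranges overlap.

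Within the miRNA reads, no miRNA passed the test. edgeR's quasi-likelihood test compared 152 miRNAs and called 0 at a 5% false discovery rate, with 11 at an unadjusted p under 0.05. DESeq2 called 2 and limma-voom 0. The lowest p belonged to miR-34a-5p, a transcriptional target of p53 (log2 fold change -3.24, SE 1.01, edgeR adjusted p = 0.607). It stood at 32.7 ± 12.4 CPM in Dicer flox/wt and 271 ± 251 CPM in Dicer wt/wt, and the wt/wt lines held 5.46, 302, 177 and 602 CPM in replicate order. DESeq2 called it lower in Dicer flox/wt (adjusted p = 0.0443), and over the settings tried its adjusted p ran from 0.0443 to 0.998 and its log2 fold change from -4.83 to -1.26. The log2 fold change of miR-34a-5p was -2.38 without wt/wt replicate 4 and -1.47 without wt/wt replicates 2 and 4. Its precursor lies at chromosome 4, 150068454 to 150068555 (mm10), outside other annotated genes of that strand.

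The other 4 of the 5 lowest p values among miRNAs with a lower fitted level in Dicer flox/wt came from 1 library. miR-10b-5p, whose precursor lies in an intron of Hoxd3 and Hoxd4 (chromosome 2, 74726070 to 74726137), had a log2 fold change of -9.18 (SE 3.08, edgeR adjusted p = 0.607). It held 77010 CPM in wt/wt replicate 4 and at most 98.6 CPM in every other library. miR-196b-5p, in an exon of Hoxa9 (chromosome 6, 52230081 to 52230165), had -6.66 (SE 2.66), with 10995 CPM in the same library and at most 92.3 CPM elsewhere. Without that library both signs turned, to 2.08 and 0.61. miR-185-5p, in an intron of Tango2 (chromosome 16, 18327401 to 18327465), had -1.79 (SE 0.73) and -0.47 without it. miR-339-5p (chromosome 5, 139369650 to 139369745, an intron of 3110082I17Rik) had -2.38 (SE 0.97) and -0.099 without it.

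Among miRNAs with a higher fitted level in Dicer flox/wt, miR-6240 (chromosome 5, 114851948 to 114852064) had the lowest p, with a log2 fold change of 5.06 (SE 1.89, edgeR adjusted p = 0.607). DESeq2 called it higher (adjusted p = 0.0214), and over the settings tried its adjusted p ran from 0.0214 to 0.998 and its log2 fold change from 3.30 to 7.77. Its level was 9656 ± 13721 CPM in Dicer flox/wt, where replicates 3 and 5 held 15624 and 31213 CPM and the others at most 646 CPM. It was 259 ± 298.6 CPM in Dicer wt/wt. miR-672-5p, in an intron of Nexmif (chromosome X, 104116175 to 104116274), had 4.31 (SE 1.79), and miR-335-5p, in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), had 4.11 (SE 1.79). miR-3470a (chromosome 6, 83090311 to 83090387) had 3.19 (SE 1.55). miR-6539, in an intron of Dock5 (chromosome 14, 67859636 to 67859745), had 2.48 (SE 1.22). miR-335-5p held 924 CPM in flox/wt replicate 5 and at most 98.4 CPM elsewhere, and had 2.26 without that library. miR-6539 had 1.65 without flox/wt replicate 3, which held 405 CPM, and miR-3470a had 5.03 without wt/wt replicate 3. miR-672-5p did not pass the filter without flox/wt replicate 2, 4 or 5. Over the settings tried the log2 fold change ran from 2.29 to 5.85 for miR-672-5p, 1.71 to 5.40 for miR-335-5p, 1.00 to 5.03 for miR-3470a and 0.40 to 3.08 for miR-6539. None of these passed edgeR's adjusted threshold. The spread between libraries was wide, with a median biological coefficient of variation of 0.906. On simulated counts with this spread the test found 0 of 17 2-fold, 3 of 24 4-fold (12.5%) and 23 of 27 16-fold (85.2%) changes among the changed miRNAs that passed the filter, so with this spread most changes of up to 4-fold would be missed.

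**Figure D2:**
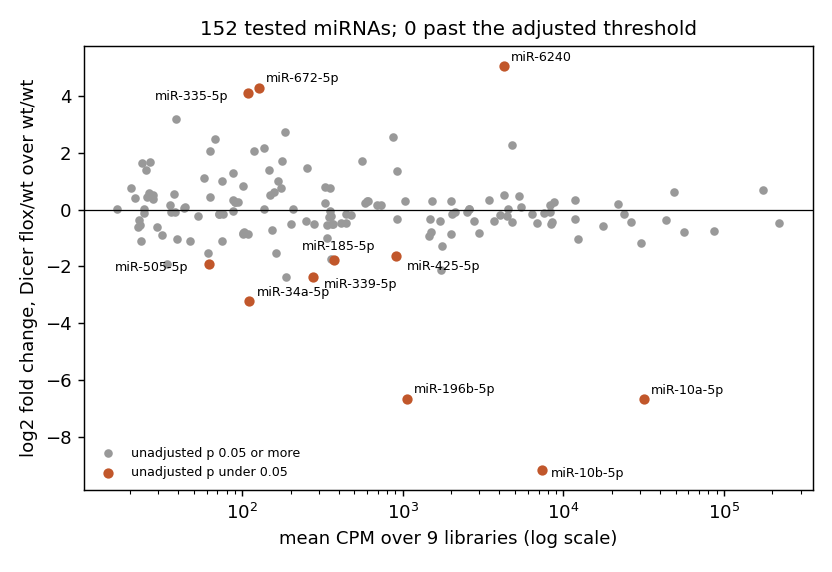
Log2 fold change between Dicer flox/wt and Dicer wt/wt (vertical axis) against mean CPM over the 9 libraries (horizontal log axis), with 1 point per tested miRNA. The 11 coloured and named miRNAs have an unadjusted p under 0.05, and none of the 152 passed the adjusted threshold.

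None of the 10 most abundant miRNAs passed edgeR's adjusted threshold. miR-21a-5p, an oncogenic miRNA whose precursor overlaps an exon of Vmp1 (chromosome 11, 86584067 to 86584158), held 281040 ± 60842 CPM in Dicer flox/wt and 149720 ± 121480 CPM in Dicer wt/wt (log2 fold change 0.71, SE 0.78). On the scale of all reads of 18 to 30 nt its sign turned (-0.37). miR-125b-5p held 142020 ± 45498 and 152020 ± 120570 CPM (log2 fold change -0.45). The fitted log2 fold changes of the other abundant miRNAs were -0.78 for miR-99b-5p, -0.75 for miR-26a-5p, -0.36 for miR-125a-5p, -1.18 for miR-191-5p, -0.43 for miR-30c-5p, -0.15 for miR-16-5p, 0.64 for miR-199a-5p and -6.68 for miR-10a-5p. With 1 library left out the values ranged from -9.29 to -0.13 for miR-10a-5p, -1.44 to -0.25 for miR-191-5p, -0.54 to -0.12 for miR-30c-5p, -0.26 to 0.13 for miR-16-5p and 0.30 to 1.07 for miR-21a-5p, with the value nearest to 0 or past it without wt/wt replicate 4. They ranged from -1.17 to 0.19 for miR-99b-5p and -0.66 to 0.033 for miR-125a-5p (past 0 without wt/wt replicate 1), -0.78 to 0.073 for miR-125b-5p (past 0 without wt/wt replicate 2) and -0.93 to -0.54 for miR-26a-5p. For miR-199a-5p the value was 4.89 without wt/wt replicate 1 and -0.56 without flox/wt replicate 1, and 0.070 to 0.12 without wt/wt replicate 2, 3 or 4. The value for miR-199a-5p was -0.38 on the scale of all reads of 18 to 30 nt. miR-451a, which Ago2 and not Dicer cuts, held 13.9 ± 6.39 and 8.64 ± 7.44 CPM from 3 to 11 reads per library and was too low to test. miR-103-3p, miR-107-3p, miR-200c-3p and miR-210-3p were not analysed here.

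None of the 13 miRNA lists with 2 or more tested members passed camera with the preset correlation (adjusted p from 0.839 to 0.901), and none did with an estimated correlation (adjusted p = 0.936 for each). For the fibroblast and smooth muscle list the median log2 fold change was 0.26, while the mean (-1.54) and camera's direction were negative. Camera's direction was also opposite to the median for the hepatocyte and gut, pancreatic cancer and X-linked miR-322 lists. On the scale of all reads of 18 to 30 nt the median of each list with a tested member lay below 0, except for hepatocyte and gut (0.93). No member of any list passed over all tested miRNAs. Adjusted over the list alone, 1 member passed, miR-34a-5p of the miR-34 family (adjusted p = 0.0208), while miR-34c-5p had a log2 fold change of -0.34. That list has 2 tested members. Each list was adjusted separately with no correction across lists, so this pass adds no support beyond the test over all miRNAs. The lowest camera p belonged to miRNAs made without Drosha, of which 3 of 4 tested members had a lower fitted value, with miR-484 at -0.81, miR-1839-5p at -0.39 and miR-1981-5p at 0.09. fry, which asks whether members move one way on balance, called this list lower (adjusted p = 0.0211). The list of miR-17~92 and related clusters, which promote proliferation, had 5 tested entries, and all had lower fitted values (median log2 fold change -0.85). They included miR-17-5p at -0.92, miR-20a-5p at -0.85 and miR-93-5p at -0.16. Other arms of these clusters, such as miR-25-5p and miR-92a-1-5p, were tested but are not in the list. Without wt/wt replicate 4, which holds 24443 CPM of this list against 1698 to 8504 CPM in the other libraries, camera called the list higher in Dicer flox/wt (adjusted p = 0.0229). 4 of the 5 miR-30 members had lower fitted values (miR-30a-5p 0.51, miR-30d-5p -0.50).

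In the miR-15/16 family 5 of 7 members had higher fitted values, with miR-15b-5p at 0.04 and miR-322-5p at 0.23. In the X-linked miR-322 cluster 3 of 5 did, with miR-351-5p at 0.49 and miR-450a-5p at -0.43. In the miR-183 cluster 2 of 3 did, with miR-182-5p at 0.34, miR-96-5p at 0.36 and miR-183-5p at -0.23. Of the oncogenic miRNAs named in pancreatic cancer 3 of 8 had higher fitted values, with miR-31-5p at -0.08 and miR-100-5p at -1.04. Of the Sfmbt2 intronic cluster, a rodent group of miRNAs, 3 of 5 did. Its miR-669a-5p and miR-669p-5p hold the same reads, so their value of 0.27 is 1 measurement, and miR-467a-5p stood at -0.17. The let-7 list had a single tested member, miR-98-5p (-0.07), and let-7 itself was not analysed here. The miR-232724, miR-29, miR-200, skeletal and cardiac muscle, and Dlk1-Dio3 lists had no tested member. Only the arms entered in a list count. Of the miR-232724 clusters, arms outside the list were tested, with miR-23b-5p at -0.87, miR-27a-5p at 0.35, miR-27b-5p at -1.12 and miR-24-2-5p at 1.36.

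The shift of all miRNAs together depended on the scale and on the method. Relative to other miRNAs, the median log2 difference over the tested miRNAs was 0.59 (exact two-sided permutation p = 0.0159, the smallest that the splits of 9 libraries allow). It was 0.33 on TMM-scaled CPM (exact permutation p = 0.0159) and 0.11 without a low-count filter (exact permutation p = 0.0794). It was 0.30 without wt/wt replicate 4 (exact permutation p = 0.0714) and 0.38 without wt/wt replicate 1 (exact permutation p = 0.143). The median of the edgeR fold changes, which also used TMM, was -0.08, and that of limma-voom was 0.42. The sign relative to other miRNAs thus differed between methods. Medians relative to other miRNAs cannot show a change of total miRNA. Relative to all reads of 18 to 30 nt, the median was -1.03 (exact permutation p = 0.127), and the median of the edgeR fold changes was -1.40. On that scale edgeR also called 0 miRNAs, with 29 at an unadjusted p under 0.05.

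More miRNAs were detected at equal depth in Dicer flox/wt, 236 ± 10.5 (SD, n = 5) against 205 ± 25.6 (SD, n = 4; exact two-sided permutation p = 0.0317). Wt/wt replicate 4 was lowest at 167, and without it the difference fell from 31.5 to 19.0 (exact permutation p = 0.0714). Without thinning to equal depth the difference was -3.4 (exact permutation p = 0.952), and with at least 5 reads required it was 13.5 (exact permutation p = 0.0159). The exact permutation p was 0.0571 without flox/wt replicate 2, 3, 4 or 5 and 0.0714 without wt/wt replicate 2 or 3. The 10 most abundant miRNAs took 74.0% ± 1.22 (SD, n = 5) and 74.8% ± 4.41 (SD, n = 4) of the miRNA reads (exact two-sided permutation p = 0.762). Wt/wt replicate 4 was lowest at 68.3%, and without it the difference was -2.80 points (exact permutation p = 0.0714). Genotype accounted for 13.5% of the variance between libraries (exact one-sided permutation p = 0.365). Only miR-143 had both arms tested, and its minor to major arm log2 ratio differed by -0.36 (exact two-sided permutation p = 0.603).

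miRNAs that mark cell types varied widely between lines of the same genotype. The fibroblast and smooth muscle list ranged from 1202 CPM in flox/wt replicate 4 to 137390 CPM in flox/wt replicate 1, and 3 of its 6 tested members had higher fitted values (miR-143-3p -0.12). The haematopoietic list ranged from 17226 to 56634 CPM in 8 libraries, mostly miR-146a-5p (log2 fold change 0.21), and was 1105 CPM in wt/wt replicate 4. miR-486a-5p (0.02) and miR-155-5p (-0.80) were its other abundant members. The hepatocyte and gut list was 17002 and 34263 CPM in flox/wt replicates 2 and 4, and 291 to 4267 CPM elsewhere. Its fitted values were 2.30 for miR-192-5p, 2.56 for miR-194-5p and -1.11 for miR-122-5p. The endothelial list, here miR-126a-5p (log2 fold change -2.38), was 1450 CPM in wt/wt replicate 4 and 27.9 to 189 CPM elsewhere. The neural list ranged from 67.5 to 1927 CPM (miR-9-5p 0.17, miR-129-5p -1.52). The pancreatic acinar and islet list ranged from 1876 to 9170 CPM, nearly all of it miR-7a-5p (log2 fold change -0.42). The miR-200 family, a marker of epithelial cells, reached at most 32.6 CPM over the 4 of its 9 listed arms that were analysed. The skeletal and cardiac muscle list reached at most 12.6 CPM, with 1 of its 7 entries analysed. The other entries were not analysed, so these levels cannot show whether those miRNAs were absent.

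**Figure D3:**
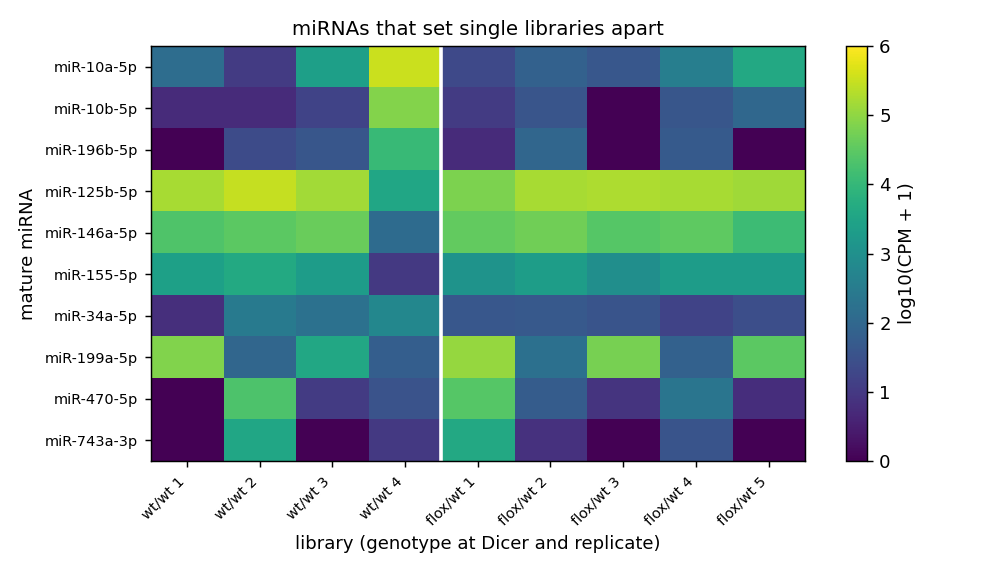
Level of 10 miRNAs as log10(CPM + 1) (colour) in each library (columns, wt/wt left and flox/wt right of the white line), with 1 miRNA per row; the 10 were chosen after their values were seen. Wt/wt replicate 4 holds 328960 CPM of miR-10a-5p, and flox/wt replicate 1 and wt/wt replicate 2 hold 26822 and 21158 CPM of miR-470-5p.

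The authors' deposited table gives its own p-values for Dicer mutant against wild type on RPM (reads per 1000000 reads of 18 to 30 nt), with no adjustment stated. Of the 704 rows with a p-value in the authors' deposited table, 19 lie under 0.05, from 17 mature names. That is fewer than 5% of the rows. The rows share the same libraries and some repeat a name, so this number cannot be weighed against chance. In the authors' deposited table, 18 of these rows have the lower mean in the Dicer mutant, such as miR-30c-5p (deposited means 1396 and 4833), miR-16-5p (1371 and 3849) and miR-484 (283 and 1479). The only row with a higher mean is miR-3470a (4.83 and 1.20). That scale is the one on which the miRNA share of the reads enters every value.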

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

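The tests of explanations in this part were all chosen after the result was seen. By a Dixon ratio, a library lay far from the rest of its genotype in 17 of 114 groups of values examined. The nominal rate of about 1 in 20 assumes normal values and groups chosen without regard to them. The groups share the same libraries. Among those flagged, miR-10b-5p, miR-185-5p and miR-339-5p had been named for low p values that came from wt/wt replicate 4. The number of flags, in all or in that library, therefore cannot be weighed against chance. 11 of the 17 were in wt/wt replicate 4, which held the lowest level of its genotype for miR-125b-5p (3599 CPM), miR-100-5p (111 CPM), miR-146a-5p (125 CPM), miR-155-5p (8.99 CPM), miR-31-5p (489 CPM) and miR-6539 (0 CPM). It held the highest for miR-10b-5p (77010 CPM), miR-126a-5p (1450 CPM), miR-185-5p (2106 CPM), miR-191-5p (130100 CPM) and miR-339-5p (2021 CPM). Flox/wt replicate 1 had the highest miRNA share of its genotype (23.7%) and the lowest miR-125b-5p (65490 CPM), miR-191-5p (13010 CPM) and miR-3470a (5.62 CPM). miR-129-5p was lowest in flox/wt replicate 3 (0 CPM, which allows up to 20.9 CPM there), and miR-93-5p was highest in flox/wt replicate 5 (4039 CPM).

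Wt/wt replicate 4 also lacked miRNAs that every other library held. 22 miRNA names, of which miR-669a-5p and miR-669p-5p hold the same reads, had 0 reads there although 3 or more were expected from the lowest share in the other 8 libraries, against at most 2 in any other library, which argues against low depth. They include miR-345-5p (151 reads expected), miR-674-5p and miR-145a-5p. Also among them are members of the rodent Sfmbt2 intronic cluster, miR-467c-5p (13.2 reads expected) and miR-669a-5p with miR-669p-5p (9.73 reads expected). Cells or RNA of another species may be a candidate explanation, and the rodent Sfmbt2 intronic cluster held 18.9 CPM there against 70.0 to 3309 CPM elsewhere. That is low but above the limit of 2.70 CPM that a count of 0 allows, a limit that covers counting error only. The sum therefore cannot tell another species from a mouse line of another cell type. Whether this library comes from a mouse line stays open. For blood cells, the haematopoietic list held 1105 CPM there against 17226 to 56634 CPM elsewhere. That sum is mostly miR-146a-5p in the other libraries (12647 to 51183 CPM, against 125 CPM here), so it cannot tell whether some blood cells were present. miR-486a-5p, at 958 CPM, lay within the 517 to 3239 CPM of the other libraries. No other biological explanation was examined.

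The lower miRNA share in Dicer flox/wt has several candidate explanations. A difference in how many reads fell within 18 to 30 nt is argued against. The percent of raw reads in that range had a ratio of 1.05 between genotypes while the shares had 0.323. Read lengths within the range were not compared, so a difference in size selection there stays open. Counting reads at several precursors is argued against too, since the log2 ratio of mean shares was -1.63 with each name counted once and -1.68 with all rows summed. Lower output from a single Dicer copy may contribute: relative to the miRNA share, miR-451a, which needs no Dicer, was higher by 0.88 (log2, SE 0.64, exact permutation p = 0.159) on 3 to 11 reads per library, which is too few to decide. Dilution by other RNA fragments stays open as well. miR-6240 served as its readout, but whether the reads of miR-6240 come from another RNA was not tested. Its RPM ran against the share over the 9 libraries (Spearman rho -0.68, permutation p = 0.0493, and Pearson r -0.65, permutation p = 0.065). However, r was -0.31 without the 2 libraries farthest from the median share. The correlation within genotypes did not pass (rank correlation -0.67, exact permutation p = 0.103, and r -0.46, exact permutation p = 0.243). miR-6240 was also picked for its low p between the genotypes.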

How the results depend on the processing

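The alternatives with wt/wt replicates 2 and 4 left out together, the most-read row per name, the combinations with reads of 18 to 30 nt, and the other share definitions were chosen after seeing the data. All causes below were not tested unless the setting itself names them. DESeq2 called 2 (miR-34a-5p -3.12 and miR-6240 5.02), and leaving out 1 library gave 0 to 1, the 1 being miR-6538 (log2 fold change 6.93) without wt/wt replicate 3, while each of the other alternatives called 0. For lists, fry called 1, leaving out 1 library gave 0 to 1 (miR-17~92 without wt/wt replicate 4), and leaving out wt/wt replicates 2 and 4 gave 2, miR-17~92 higher and Dlk1-Dio3 lower. The Dlk1-Dio3 list has no tested member with all libraries, and of the 2 wt/wt libraries left only replicate 1 holds it (9568 CPM, against 0 in replicate 3), so that call rests on 1 wt/wt library. Against the median edgeR log2 fold change of -0.08, the median was 0.25 with CPM, 0.42 with voom and -1.40 with reads of 18 to 30 nt as library size.

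The difference in miRNA share kept its sign throughout, at -15.3 to -27.6 points with 1 library left out, -20.4 permuted within the title series (exact permutation p = 0.0333), -8.03 over all raw reads (exact permutation p = 0.0952) and -16.6 without wt/wt replicates 2 and 4 (exact permutation p = 0.19). The difference in miRNAs detected was 19.0 to 38.1 with 1 library left out and 17.0 without wt/wt replicates 2 and 4 (exact permutation p = 0.19), and -3.4 without thinning (exact permutation p = 0.952). The smallest p with a library left out is 0.0286 or 0.0357, so a loss of the call there follows partly from fewer splits. Without wt/wt replicates 2 and 4 only 21 splits remain. Their smallest two-sided exact permutation p is 0.0952, so no such difference could pass there. The median log2 difference was 0.30 to 0.64 with 1 library left out and 0.27 without wt/wt replicates 2 and 4 (exact permutation p = 0.381). It was 0.33 on TMM-scaled CPM, 0.50 with a prior count of 5, 0.11 without a low-count filter and -1.03 with reads of 18 to 30 nt. The difference in the share of the 10 most abundant was -2.80 to 0.42 with 1 library left out, 8.78 for the 5 and 0.0062 for the 20 most abundant. Without wt/wt replicates 2 and 4 it was -3.47 for the 10 most abundant (exact permutation p = 0.0952). The arm ratio of miR-143 was -0.77 to 0.017 with 1 library left out. The variance explained by genotype kept its side of the threshold in each setting. Mapped reads as denominator, and hairpins with 100 reads in every library, could not be run because the first is not in the tables used here and no hairpin met the second.

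Of 1469 log2 fold changes of the named miRNAs under an alternative, 1278 kept their sign, 191 did not, and 2 passed the threshold. 17 of 53 named miRNAs kept their sign in every alternative. With reads of 18 to 30 nt as library size the opposite signs were miR-146a-5p -0.98, miR-15b-5p -1.33, miR-182-5p -0.65, miR-1981-5p -1.50, miR-199a-5p -0.38, miR-21a-5p -0.37, miR-30a-5p -0.80, miR-322-5p -0.79, miR-351-5p -0.86, miR-486a-5p -1.47, miR-669a-5p -2.02, miR-669p-5p -2.02, miR-9-5p -1.03, miR-96-5p -0.95. Without wt/wt replicate 2 on that scale they were miR-146a-5p -0.37, miR-15b-5p -1.28, miR-182-5p -0.17, miR-1981-5p -0.88, miR-199a-5p -0.80, miR-21a-5p -0.20, miR-30a-5p -0.78, miR-322-5p -0.35, miR-351-5p -0.11, miR-467a-5p 2.02, miR-486a-5p -0.24, miR-9-5p -1.24, miR-96-5p -0.31. Without wt/wt replicate 4 on it they were miR-10b-5p 0.52, miR-146a-5p -1.39, miR-15b-5p -1.13, miR-182-5p -0.80, miR-1981-5p -1.91, miR-199a-5p -0.80, miR-21a-5p -0.77, miR-30a-5p -0.64, miR-322-5p -0.74, miR-351-5p -1.28, miR-486a-5p -1.71, miR-669a-5p -2.44, miR-669p-5p -2.44, miR-96-5p -1.07. Without both on it they were miR-10b-5p 0.63, miR-146a-5p -0.95, miR-15b-5p -0.92, miR-17-5p 0.38, miR-182-5p -0.23, miR-196b-5p 0.61, miR-1981-5p -1.46, miR-199a-5p -1.38, miR-20a-5p 0.59, miR-21a-5p -0.76, miR-30a-5p -0.52, miR-351-5p -0.69, miR-467a-5p 1.43, miR-486a-5p -0.19, miR-96-5p -0.18. With the title series as block on it they were miR-146a-5p -0.87, miR-15b-5p -1.55, miR-182-5p -0.83, miR-1981-5p -1.21, miR-21a-5p -0.31, miR-30a-5p -0.97, miR-322-5p -1.46, miR-351-5p -0.93, miR-486a-5p -1.53, miR-669a-5p -0.86, miR-669p-5p -0.86, miR-9-5p -2.39, miR-96-5p -0.98.

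On the scale of the miRNA reads, the opposite signs without wt/wt replicates 2 and 4 were miR-10b-5p 1.76, miR-126a-5p 0.44, miR-146a-5p -0.22, miR-16-5p 0.11, miR-17-5p 0.75, miR-196b-5p 0.80, miR-1981-5p -0.41, miR-199a-5p -0.52, miR-20a-5p 0.85, miR-21a-5p -0.0042, miR-30d-5p 0.0082, miR-467a-5p 3.11, miR-93-5p 0.30. In the 4-digit series alone they were miR-10b-5p 1.49, miR-126a-5p 0.53, miR-16-5p 0.25, miR-17-5p 1.23, miR-183-5p 0.23, miR-1839-5p 0.76, miR-196b-5p 1.21, miR-1981-5p -0.39, miR-20a-5p 1.58, miR-486a-5p -0.045, miR-669a-5p -0.067, miR-669p-5p -0.067, miR-93-5p 0.51. In the 5-digit series alone they were miR-100-5p 0.43, miR-125a-5p 0.052, miR-125b-5p 0.47, miR-143-3p 0.63, miR-146a-5p -0.34, miR-155-5p 0.41, miR-15b-5p -0.86, miR-182-5p -0.39, miR-30a-5p -0.33, miR-31-5p 0.29, miR-322-5p -1.85, miR-34c-5p 1.07, miR-351-5p -0.63, miR-486a-5p -0.44, miR-9-5p -5.11, miR-98-5p 0.042, miR-99b-5p 0.0012. The title series as block gave miR-143-3p 0.30, miR-31-5p 0.026, miR-34c-5p 0.16, miR-467a-5p 0.96, miR-486a-5p -0.0069, miR-9-5p -0.48, miR-93-5p 0.047, miR-98-5p 0.020. limma-voom gave miR-100-5p 0.62, miR-125b-5p 0.67, miR-129-5p 0.16, miR-143-3p 1.03, miR-155-5p 1.07, miR-17-5p 0.014, miR-20a-5p 0.27, miR-31-5p 0.80, miR-34c-5p 0.39, miR-467a-5p 0.84, miR-93-5p 0.025, miR-98-5p 0.54. Plain CPM gave miR-143-3p 0.35, miR-16-5p 0.051, miR-31-5p 0.28, miR-34c-5p 0.18, miR-467a-5p 0.45, miR-98-5p 0.29. No low-count filter gave miR-15b-5p -0.0014, miR-1981-5p -0.035, miR-486a-5p -0.049. miR-467a-5p also turned to 0.058 with DESeq2 size factors, 0.28 with the upper quartile, 0.080 with the DESeq2 test, 0.030 without the 5 most abundant and 0.018 with the most-read row.

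With 1 library left out, the ranges of those whose sign turned were miR-10b-5p -9.79 to 2.08, miR-125a-5p -0.66 to 0.033, miR-125b-5p -0.78 to 0.073, miR-126a-5p -3.18 to 0.39, miR-129-5p -2.02 to 0.44, miR-143-3p -0.64 to 0.87, miR-146a-5p -0.15 to 0.51, miR-15b-5p -0.18 to 0.33, miR-16-5p -0.26 to 0.13, miR-17-5p -1.26 to 0.69, miR-1839-5p -0.66 to 0.14, miR-196b-5p -7.31 to 0.61, miR-1981-5p -0.33 to 0.41, miR-199a-5p -0.56 to 4.89, miR-20a-5p -1.24 to 0.88, miR-31-5p -0.45 to 0.28, miR-322-5p -0.23 to 0.61, miR-34c-5p -0.61 to 0.48, miR-467a-5p -0.33 to 3.83, miR-486a-5p -0.29 to 0.61, miR-669a-5p -1.24 to 3.75, miR-669p-5p -1.24 to 3.75, miR-7a-5p -0.69 to 0.062, miR-9-5p -1.59 to 3.24, miR-93-5p -0.42 to 0.42, miR-98-5p -0.47 to 0.67, miR-99b-5p -1.17 to 0.19. None of these named miRNAs passed the threshold in edgeR's test with all libraries, so a turned sign there ends no call.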

Other observations

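15 mature miRNAs of a cluster on the X chromosome, with 16 precursors between 66776757 and 66839125 (mm10), were abundant in a single line of each genotype. The cluster was chosen after its values were seen, as were the tests in this part. miR-470-5p held 26822 CPM in flox/wt replicate 1 and 21158 CPM in wt/wt replicate 2, and at most 216 CPM in every other library. miR-465c-5p held 9433 and 8347 CPM against at most 37.6 CPM, and miR-743a-3p held 4087 and 3593 CPM against at most 35.1 CPM. The Dlk1-Dio3 cluster, an imprinted group, was 9568 CPM in wt/wt replicate 1, 1736 and 1147 CPM in flox/wt replicates 4 and 5, and at most 6.98 CPM elsewhere. miR-199a-5p, a miRNA of mesenchymal cells, held 113930 CPM in flox/wt replicate 1 and 73632 CPM in wt/wt replicate 1 but 97.0 CPM in wt/wt replicate 2.

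A single cell line sequenced under both labels could give the X-linked pattern, but 19 miRNAs above 100 CPM in either of those libraries differed by 10-fold or more between them, which argues against it. The highest member exceeded the lowest by 146-fold or more in each of the libraries, so the members do not all hold the same reads. Names of 1 stem lay closer, with miR-465a-5p, miR-465b-5p and miR-465c-5p at 4877, 6674 and 9433 CPM in flox/wt replicate 1. In wt/wt replicate 2 they held 3794, 4139 and 8347 CPM, and reads shared among such near-identical copies were not tested. No biological explanation was tested.

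The splits of the 9 libraries cannot show whether chance could give the genotype result. The real split called 0 miRNAs with edgeR (11 at an unadjusted p under 0.05; DESeq2 called 2 and limma-voom 0), and no split can call fewer, so 100 of 100 drawn splits give as many whatever the data. The highest other gave 2. The same holds on the scale of reads of 18 to 30 nt (real 0, 100 of 100, highest other 85) and for lists (real 0, 100 of 100, highest other 3). The split with 85 calls sets flox/wt replicates 2 to 5 and wt/wt replicate 3 against the rest, the libraries with the lower miRNA shares against those with the higher, and the share enters every value on that scale.

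In the authors' deposited table the average headed p53 wild type is the value of wt/wt replicate 2 alone. miR-34a-5p, a p53 target, held 302 CPM there, between the 177 and 602 CPM of wt/wt replicates 3 and 4, and 5.46 CPM in wt/wt replicate 1.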
